A study of Mus musculus with 6 samples.

How the data were processed

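RNA was sequenced from mouse CD8+ T cells kept in medium with palmitate or in control medium, with 3 libraries per group. Per the labels' protocols, total RNA was purified on RNeasy columns and made into libraries with a SMARTER mRNA-Seq kit. The submitters' processing notes name Trim Galore 0.6.10, Salmon 1.10.0, DESeq 1.42.0 and the mouse build GRCm39, without saying which step used which setting, and the strand setting is not given in the sources used here. The authors deposited a gene matrix of whole-number estimated counts for the whole series, and for each library a Salmon table of transcripts, whose expected counts need not be whole and whose other deposited columns, such as TPM, were not used here. No column of the gene matrix was left unused (0 columns), and 0 entries named no gene.

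Gene symbols were taken from the GENCODE M21 annotation and a table of gene names, which gave a symbol to 29087 of the 29370 gene identifiers in the matrix. That annotation belongs to an earlier mouse build than the one the submitters name, so no coordinates are printed. Of the 116224 transcripts in each library's table, 114857 (98.82%) were matched to a gene, and these held 99.45% to 99.49% of the reads. The gene matrix did not hold all of those reads. It equalled the sum of a gene's transcripts to within 1.5 reads for 23526 of 29131 genes (80.8%). Of 9847 genes with at least 500 reads in all, 1935 had under 90% of their transcript reads in the matrix, 819 under 50%, and 16 over 110%. A further 171 genes with at least 500 transcript reads were absent from the matrix. Which table linked transcripts to genes when the matrix was made is not given in the sources used here. Where a named gene was counted in part, the share is given beside it.

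Genes were tested in R 4.3.3 with edgeR 4.0.16 on the matrix counts, using TMM scaling, edgeR's filter on low counts, a robust quasi-likelihood fit and the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The filter left 12068 genes. All 6 libraries entered the fit, with the group as the single term. Log2 fold changes are palmitate over control with their standard errors (SE), and CPM values are counts scaled to a common total on TMM-scaled library sizes (edgeR's cpm), given as mean ± SD with n = 3 libraries per group. Every adjusted p for a gene in the text comes from this test unless another is named. Salmon divides reads shared by near-identical transcripts, so values of paralogous families (guanylate-binding proteins, p200 genes, histocompatibility genes, immunoglobulin and ribosomal protein genes) are uncertain to that extent, as are values of overlapping antisense pairs.

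A total of 35 gene lists was fixed before the data were examined, 27 for cell programs and 8 for other cell types. They hold 766 entries, of which 762 matched the matrix; the unmatched 4 were Atp5mj, Atp5mk, Atp5if1 and Rigi. Some genes stand in more than 1 list, such as Cpt1a and Slc25a20, so the lists are not independent. Lists with at least 5 tested members were compared with the other genes by limma 3.58.1's camera test with a preset correlation of 0.01, adjusted over the lists, and then with a correlation estimated for each list. Fry was a further alternative. The genes named were set by a rule: the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of 2 or more, an ordinary symbol and groups that did not overlap; up to 4 members of each list with the smallest adjusted p; 9 genes always reported (Cpt1a, Pdk4, Plin2, Gzmb, Ifng, Prf1, Tnf, Pdcd1, Tcf7); and up to 10 genes of families in the closing section. Some genes that the rule selects, and 1 of the gene families tested, are not reported here. Members that moved against most of their list, where 5 or fewer did so, were named after their values were seen, as were Nqo1, Ighm, Gbp6, Gbp5 and Cct6a.

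Replicate numbers 1 to 3 stand in the labels of both groups. Deviations from the group means correlated across genes at 0.20, 0.11 and 0.14 between libraries of the same number, and at −0.18 to 0.05 between libraries of different numbers. By the rule set at that time, all 3 same-number values being over 0.1, the numbers were treated as pairing the libraries. The main fit leaves this pairing out and called 2759 genes, and a fit with the number as a block, run beside it, called 3993. Values of the block fit stand beside a result where they change the call or move a count by over 1.5 times. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Counts differed between replicates of a group by more than sampling noise, with a chi-square per gene of 11.5 to 37.6, so each library was counted as 1 replicate.

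Other settings written down in advance were RLE and upper-quartile scaling, no filter on low counts, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate block, gene sums of the transcript estimates with effective-length offsets (rounded to whole numbers), and each library left out in turn. Settings chosen after seeing the data were transcript sums without the offsets, restriction to genes with 90% to 110% of their transcript reads in the matrix, removal of a GC content trend, that removal with the block, and removal of genes with a sense B2 match. B2 and B1 are short interspersed repeats. A match means at least 1 stretch of 21 bases shared between a gene's most-read transcript and a consensus of the repeat, written from general knowledge of the family; 12010 tested genes (99.5%) could be searched.

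The procedure was tested on simulated counts for the 12068 genes, of which 200 were changed. The changed genes were drawn only from those above a minimum mean log2 CPM, so the shares recovered do not cover genes with the fewest counts. Counts were drawn independently for each gene, and fewer genes were changed than were called in the data. For palmitate against control, edgeR called 52% of genes changed 1.5-fold, 80% of those changed 2-fold, 98% of those changed 4-fold and 96% of those changed 8-fold, and 8.9% of its calls were unchanged genes. DESeq2 recovered more of the 1.5-fold changes (70%) with 18.6% of its calls unchanged. The tables were made with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and bootstrap intervals rest on 10000 draws, or 100000 for the ratio of summed gains.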

Results

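The study asked how palmitate, a saturated long-chain fatty acid, affects CD8+ T cells, the lymphocytes that kill infected and tumour cells. Cells from the pancreas, spleen and lymph nodes of wild-type mice were kept in T cell medium, and RNA was sequenced after 48 h of treatment. There were 3 palmitate libraries (100 µM) and 3 control libraries. What the control medium held in place of palmitate is not given in the sources used here. The gene counts summed to 28893965, 26042768 and 29362276 in control libraries 1 to 3 and to 23843158, 24777611 and 16724588 in palmitate libraries 1 to 3. Mitochondrially encoded genes took 0.899% to 1.07% of the counts in the control libraries and 0.958% to 1.14% in the palmitate libraries. The first principal component held 42% of the variance and parted the groups.

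Palmitate-treated cells held more RNA of the lists of PPAR target genes and of naive and memory T cell genes, and less of the cell cycle and glycolysis lists. These list calls were lost with an estimated correlation (adjusted p = 0.268 to 0.429). Cpt1a, which encodes the enzyme that admits long-chain fatty acids to mitochondrial oxidation, rose from 21.1 ± 1.18 CPM to 80.6 ± 14.8 CPM (SD, n = 3 each) in the gene matrix, which held 60.3% of its transcript reads; in the transcript sums with length offsets the log2 rise was 0.50. Gzmb, which encodes the cytotoxic protease granzyme B, fell from 6769 ± 1100 CPM to 4082 ± 483 CPM and was called in 5 of the 6 fits that each left out 1 library. Of 12068 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2759, of which 1343 rose and 1416 fell. With upper-quartile scaling the split was 1651 higher and 1052 lower. At least 2-fold changes were found in 436 genes, 312 up and 124 down. The count of called genes was 1353 without control 2, 690 without control 3, 1443 without palmitate 1, 1651 without palmitate 2, 1304 without palmitate 3, and 3433 without control 1. The 2-fold count was 274 without control 2 and 197 without control 3. For genes chosen by the rule, the number of the 6 leave-one-out fits that kept a call is given where it was under 6.

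Among the largest rises at a mean log2 CPM of 2 or more were genes of antibody-secreting cells. Igha, the constant region of immunoglobulin A, rose by 3.19 ± 0.55 (SE) on the log2 scale (adjusted p = 0.0129, kept in 5 of 6 fits), and Jchain, which joins immunoglobulin chains, rose by 2.45 ± 0.31 (adjusted p = 0.00378). Klf2, a transcription factor of quiescent T cells, rose by 2.21 ± 0.42 (adjusted p = 0.013, kept in 5 of 6 fits). Gbp11, an interferon-inducible GTPase, rose by 1.98 ± 0.31 (adjusted p = 0.00764). The other rises chosen by size were Mturn (1.98 ± 0.48), the potassium channel gene Kcna2 (1.87 ± 0.43) and Hsd11b1 (1.87 ± 0.32), a glucocorticoid-activating enzyme, besides Cpt1a. Mturn and Kcna2 were each called in 2 of the 6 leave-one-out fits and Hsd11b1 in 5.

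The largest falls by the same rule were in Aldh1a3 (−2.13 ± 0.29), Tspoap1 (−1.93 ± 0.19; −2.75 in the transcript sums with length offsets), the zinc importer gene Slc39a10 (−1.81 ± 0.17), Pramel4 (−1.73 ± 0.26), Ptcra (−1.72 ± 0.15), Ifi211 (−1.69 ± 0.31, kept in 5 of 6 fits), Hopx (−1.63 ± 0.27) and the glutamate transporter gene Slc1a2 (−1.63 ± 0.23). Slc39a10 fell from 283.1 ± 69.5 to 80.7 ± 1.3 CPM. The transcripts of Aldh1a3, Pramel4 and Ptcra carry a match to the B2 repeat in sense orientation. Of the 451 tested genes with such a match, 30 rose and 167 fell (37%), whereas 10.8% of the 11559 searched genes without one fell. Of the 124 genes that fell at least 2-fold, 122 were searched and 48 carried a sense B2 match. The median log2 fold change was −0.28 (95% bootstrap interval −0.35 to −0.23) with a sense match and 0.03 without.

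**Figure D1:**
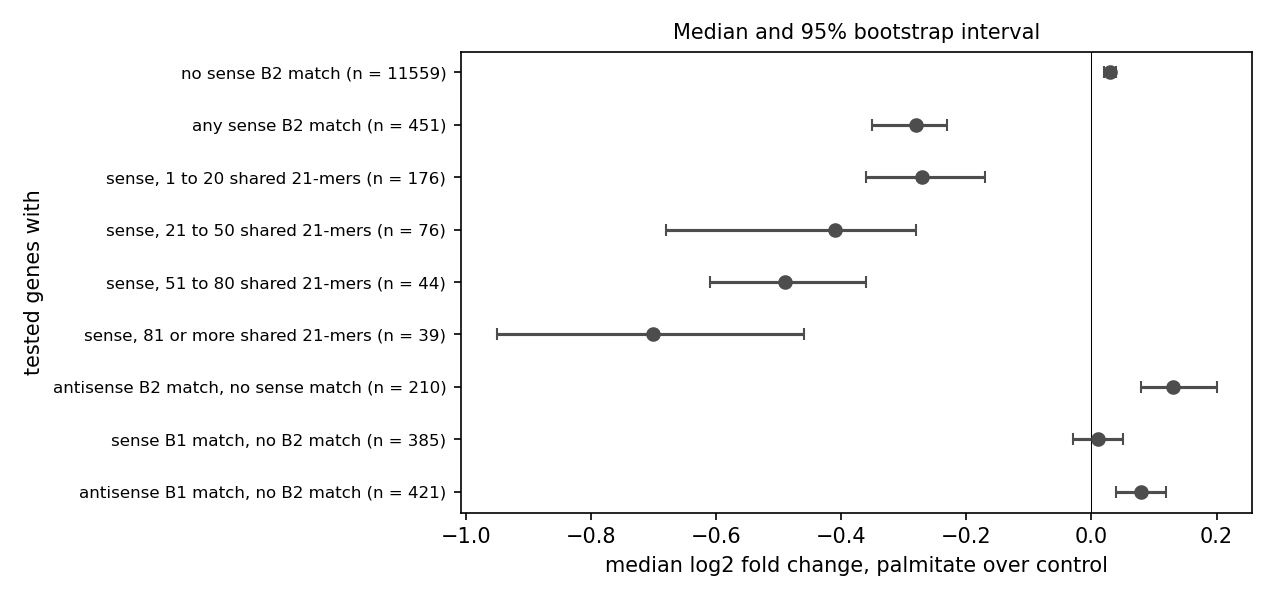
Median log2 fold change, palmitate over control (horizontal axis), of tested genes grouped by their match to the B2 or B1 repeat (vertical axis, n genes each), with 95% bootstrap intervals. Medians were −0.27 to −0.70 in the 4 groups ordered by how many 21-base stretches they shared in sense with the younger B2 consensus, and 0.13 for antisense B2 matches.

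Genes of fatty acid use were higher with palmitate. In the mitochondrial fatty acid oxidation list, 6 of 21 tested genes rose and 1 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00761, and adjusted p = 0.268 with an estimated correlation); with the block 8 rose and 2 fell. The list's adjusted p was 0.158 in the transcript sums with length offsets and 0.121 with limma-voom. Acadvl, the first dehydrogenase of long-chain oxidation, rose by 1.07 ± 0.07 (adjusted p = 0.00113), from 60.2 ± 1.9 to 126.3 ± 5.06 CPM. The carnitine carrier gene Slc25a20 rose by 0.55 ± 0.08 and Etfdh by 0.39 ± 0.08 (kept in 5 of 6 fits), while Etfa, an electron carrier, fell by 0.30. Of 14 PPAR target genes, 6 rose and 1, the fatty acid-binding protein gene Fabp5 (−0.27), fell (9 and 1 adjusted over the list alone; adjusted p = 1.39e-06, and adjusted p = 0.268 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, rose by 2.53 ± 0.40 (adjusted p = 0.00627) at a low level, 0.186 ± 0.082 to 1.08 ± 0.184 CPM. Plin2, a lipid droplet coat protein gene, rose by 1.36 ± 0.12 (adjusted p = 0.00185), from 14.9 ± 2.07 to 38.4 ± 3.19 CPM.

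Cpt1a rose by 1.93 ± 0.13 on the log2 scale in the gene matrix (adjusted p = 0.00113), which held 60.3% of its transcript reads. In the transcript sums with length offsets its log2 fold change was 0.50 (adjusted p = 0.0152). Its transcript ENSMUST00000025835 went from 18.8 ± 1.31 to 74.8 ± 14.8 CPM, and ENSMUST00000235968 went from 31.6 ± 5.3 to 24.5 ± 6.8 CPM. The value of 0.50 differs from that of the matrix by the added reads and by the length offsets, whose shares are not given here.

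**Figure D2:**
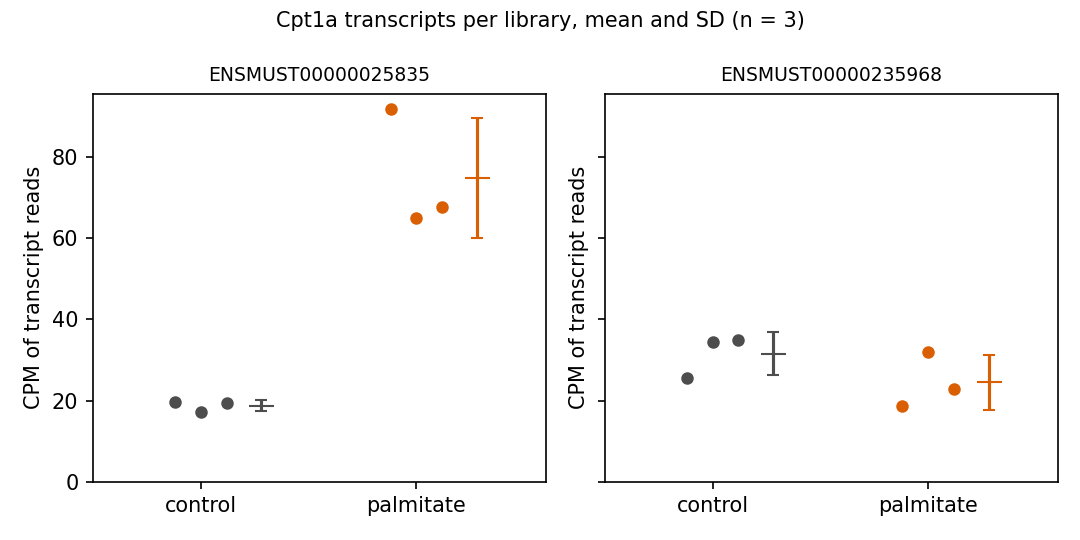
Reads of 2 Cpt1a transcripts in CPM (vertical axis) in each control and palmitate library (points), with mean and SD (bars, n = 3). The 3 palmitate libraries lie at 65.0 to 91.8 CPM for the first transcript, above the control libraries at 17.3 to 19.7 CPM.

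In lipid storage and synthesis single genes changed in both directions. Of 17 lipid droplet and triglyceride genes, Plin2 rose and the monoglyceride lipase gene Mgll fell by 1.27 ± 0.19, without passing in the transcript sums with offsets (−0.89, adjusted p = 0.074). The counts were 1 and 1 adjusted over the list alone (list adjusted p = 0.57), and with the replicate block 3 rose and 3 fell. Of 16 fatty acid synthesis genes, Srebf1 rose by 0.35 ± 0.08 (kept in 2 of 6 fits), and Elovl6, a fatty acid elongase gene, fell by 0.83 ± 0.12, as did Me1 by 1.53 ± 0.40 (kept in 1 of 6 fits). Adjusted over the list alone the counts were again 1 and 2, and with the block 2 rose and 4 fell. That list's adjusted p was 0.136, but 0.0478 with no filter on low counts and 0.0467 without control 1. Of 25 cholesterol synthesis and uptake genes, 4 fell, among them Stard4 by 0.64 ± 0.15 and Sqle by 0.31 ± 0.09, each kept in 1 of 6 fits (0 adjusted over the list alone, with 1 higher and 8 lower at an unadjusted p under 0.05 in edgeR, 6 lower by DESeq2 and 3 lower by voom). Its adjusted p was 0.0351, but 0.489 with an estimated correlation, 0.0562 with the block, 0.0574 with upper-quartile scaling, 0.0991 at a minimum of 5 CPM and 0.0839 without control 2; with the block 1 gene rose and 6 fell.

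The respiratory chain lists did not pass the list test, while several mitochondrial maintenance genes fell. None of the 13 mitochondrially encoded subunits passed edgeR's test over all genes or adjusted over the list alone (0 and 0). At an unadjusted p under 0.05 there were 2 lower, DESeq2 called 2 lower, voom 0, and the block 2 lower; the list's adjusted p was 0.344, and 0.0162 without control 1. Of 35 nuclear complex I genes 3 rose (1 adjusted over the list alone; adjusted p = 0.679), with Ndufa3 rising by 0.47 ± 0.10 (kept in 4 of 6 fits). Of 25 genes of complexes II, III and IV, 1 rose and 4 fell (1 and 3 adjusted over the list alone; adjusted p = 0.165, 0.0495 in the transcript sums with offsets and 0.0478 with no filter on low counts), with Uqcrfs1 falling by 0.40 ± 0.07 (kept in 5 of 6 fits) and cytochrome c, Cycs, by 0.57 ± 0.14 (kept in 2 of 6 fits). Of 15 ATP synthase genes 4 fell, and again 4 adjusted over the list alone (adjusted p = 0.286), and with the block 1 rose and 4 fell. Among them Atp5g1 fell by 0.33 ± 0.07 (kept in 4 of 6 fits), with a value of 0.07 in the transcript sums with offsets.

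In the list of mitochondrial biogenesis, fusion, fission and mitophagy, 1 of 25 genes rose and 7 fell (1 and 11 adjusted over the list alone; adjusted p = 0.00998, and adjusted p = 0.403 with an estimated correlation); with the block 1 rose and 11 fell. Tfam, which maintains mitochondrial DNA, fell by 0.42 ± 0.08 and the chaperonin gene Hspe1 by 0.50 ± 0.10, each kept in 5 of 6 fits. Pink1, which encodes a kinase that marks damaged mitochondria, rose by 0.98 ± 0.18 (adjusted p = 0.00987). Of 38 mitochondrial ribosomal protein genes 2 rose and 11 fell (2 and 13 adjusted over the list alone; adjusted p = 0.00263, and adjusted p = 0.489 with an estimated correlation). Mrpl1 fell by 0.66 ± 0.12 and Mrpl27, which carries a sense B2 match, by 0.46 ± 0.07, while Mrpl24 rose by 0.45 ± 0.07. Of 19 tricarboxylic acid cycle genes 1 rose and 6 fell (1 and 8 adjusted over the list alone), with Dlst, counted at 63.9% of its reads, falling by 0.34 ± 0.07 (kept in 4 of 6 fits) and Pdha1 by 0.34 ± 0.08 (kept in 2 of 6 fits). That list's adjusted p was 0.0351, and adjusted p = 0.403 with an estimated correlation. It was 0.0688 with upper-quartile scaling, 0.0948 at a minimum of 5 CPM, 0.0557 without control 2, 0.0687 without control 3 and 0.274 without palmitate 1.

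Glycolysis genes were lower with palmitate. Of 21 tested, 7 fell and 0 rose (8 and 0 adjusted over the list alone; edgeR at an unadjusted p under 0.05, DESeq2 and voom also gave 0 rises), with a camera adjusted p = 2.27e-04 and an adjusted p = 0.429 with an estimated correlation. Hexokinase 2, Hk2, fell by 1.03 ± 0.14 (adjusted p = 0.00489), from 316.3 ± 46.1 to 155.5 ± 23.4 CPM. The glucose transporter gene Slc2a3 fell by 0.53 ± 0.09, and lactate dehydrogenase A, Ldha, by 0.45 ± 0.09 (kept in 5 of 6 fits). Of 19 hypoxia-inducible genes 2 rose and 1 fell (2 and 0 adjusted over the list alone; adjusted p = 0.458, and 0.0136 without control 1), with Ndrg1 rising by 0.83 ± 0.15 (kept in 5 of 6 fits); with the block 3 rose and 6 fell.

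**Figure D3:**
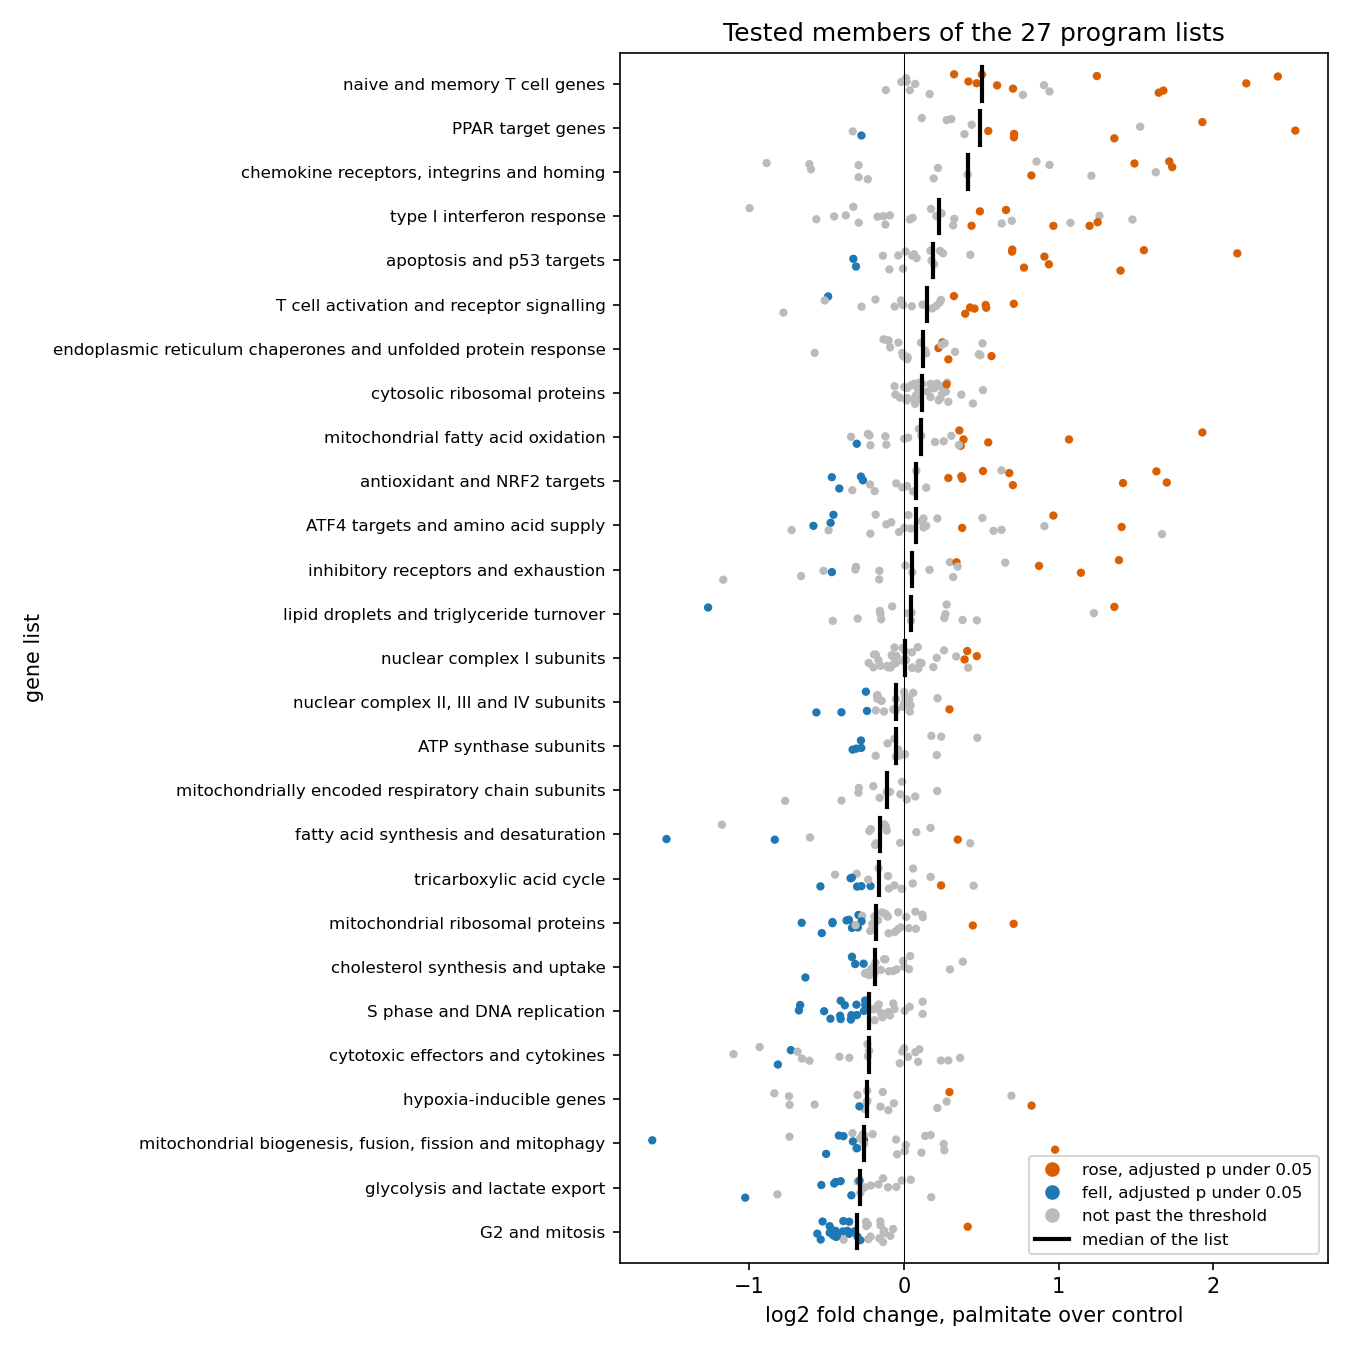
Log2 fold change, palmitate over control (horizontal axis), of each tested member of the 27 program lists (vertical axis), coloured by its call, with the list median as a black bar. Medians run from −0.30 for G2 and mitosis to 0.51 for naive and memory T cell genes.

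Genes of naive and memory T cells were higher with palmitate, with 11 of 21 risen and 0 fallen (12 and 0 adjusted over the list alone; 0 falls also at an unadjusted p under 0.05, with DESeq2 and with voom). The camera adjusted p was 1.88e-06, and adjusted p = 0.268 with an estimated correlation. Tcf7, the transcription factor TCF-1 of memory precursors, rose by 0.51 ± 0.10 (adjusted p = 0.0113, kept in 5 of 6 fits), from 69.1 ± 7.22 to 98.0 ± 7.55 CPM. Klf3, with 88.1% of its reads in the matrix, rose by 1.25 ± 0.16, Bcl6 by 1.68 ± 0.26 and the costimulatory receptor gene Cd27 by 0.71 ± 0.11. Il6ra rose by 2.42 ± 0.33, with 24% of its reads in the matrix and a sense B2 match. Summed over the 12 tested B cell and plasma cell markers, expression was also higher, at 213.9 ± 33.0 CPM in control and 292.7 ± 14.5 CPM in palmitate libraries. Chemokine receptor, integrin and homing genes included rises, with 4 of 17 risen and 0 fallen (4 and 0 adjusted over the list alone; 2 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom). Ccr9, which carries a sense B2 match, rose by 1.74 ± 0.15, Cxcr6 by 1.72 ± 0.15, Cxcr4 by 1.49 ± 0.15 and Gpr183 by 0.83 ± 0.10. The list's adjusted p was 0.00343, adjusted p = 0.268 with an estimated correlation and 0.083 with limma-voom; with the block 10 rose and 4 fell.

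Of 22 cytotoxic effector and cytokine genes 2 fell and 0 rose (2 and 0 adjusted over the list alone, with 1 rise at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom). Gzmb fell by 0.73 ± 0.14 (adjusted p = 0.0113) and Klrk1, the gene of the activating receptor NKG2D, by 0.81 ± 0.13 (adjusted p = 0.00617). Ifng, encoding interferon gamma, did not pass, with a log2 fold change of −1.10 ± 0.39 (adjusted p = 0.101; 0.00228 with the block) and 2424 ± 1090 against 1130 ± 308 CPM. Prf1, encoding perforin, had a log2 fold change of −0.66 ± 0.23 (adjusted p = 0.0748), but the matrix held 7.3% of its reads; in the transcript sums with offsets the value was −1.01 (adjusted p = 0.00328). Tnf had a log2 fold change of 0.09 ± 0.15 (adjusted p = 0.677), at 127.4 ± 22.1 and 135.8 ± 17.3 CPM. The list's adjusted p was 0.156, but 0.0225 with the block, which had 1 rise and 8 falls, and 0.0215 without control 1.

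**Figure D4:**
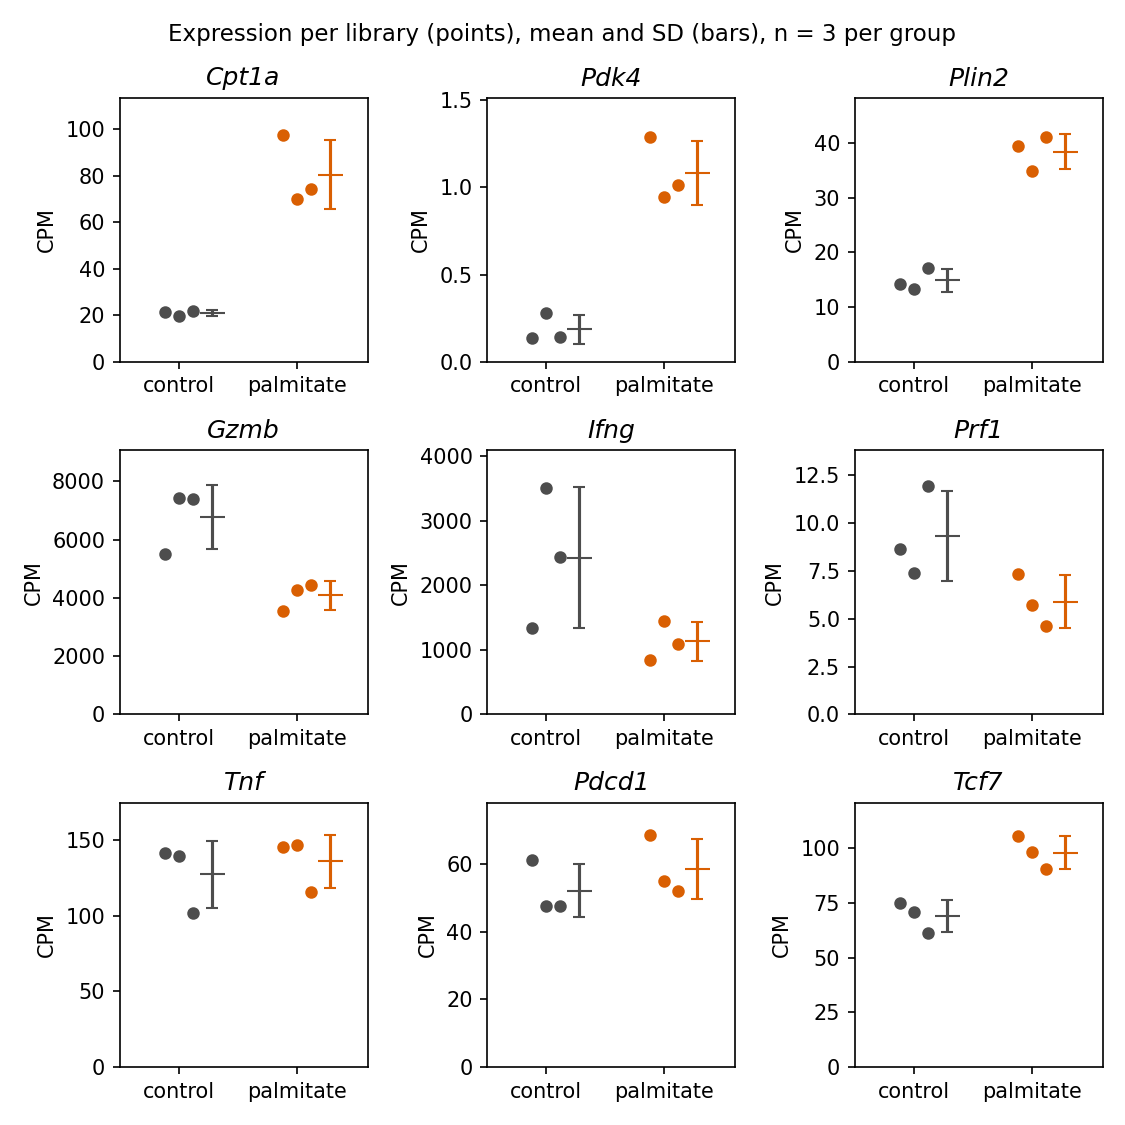
Expression in CPM (vertical axes, from 0) of the 9 genes always reported, in each control and palmitate library (points), with mean and SD (bars, n = 3). The groups lie apart for Cpt1a, Pdk4, Plin2, Gzmb, Prf1 and Tcf7, and overlap for Ifng, Tnf and Pdcd1.

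Inhibitory receptor and exhaustion genes changed in part. Of 19, 4 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.344), and with the block 7 rose and 3 fell. Vsir, encoding the checkpoint protein VISTA, rose by 1.15 ± 0.16, the ectonucleotidase CD73 gene Nt5e by 1.39 ± 0.30 (kept in 4 of 6 fits), and Tox by 0.87 ± 0.16 (kept in 5 of 6 fits), while Batf fell by 0.47. Pdcd1, encoding PD-1, had a log2 fold change of 0.17 ± 0.14 (adjusted p = 0.411). Of 22 T cell activation and receptor genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.136), and with the block 8 rose and 3 fell. Cd3d rose by 0.53 ± 0.10 (kept in 5 of 6 fits) and Cd8a, counted at 79.5% of its reads, by 0.71 ± 0.14 (kept in 3 of 6 fits). The activation-induced receptor gene Tnfrsf9 fell by 0.49 ± 0.09 (kept in 5 of 6 fits).

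Cell cycle genes were lower with palmitate. Of 32 S phase and replication genes 16 fell and 0 rose (16 and 0 adjusted over the list alone; 0 rises also at an unadjusted p under 0.05, by DESeq2 and by voom), with an adjusted p = 5.09e-07 and an adjusted p = 0.268 with an estimated correlation. Cyclin E1, Ccne1, fell by 0.67 ± 0.07 (adjusted p = 0.00254) and Ccne2 by 0.68 ± 0.11. Of 33 G2 and mitosis genes 17 fell and 1, the condensin gene Ncapd2 (0.41), rose (22 and 1 adjusted over the list alone; adjusted p = 2.53e-08, and adjusted p = 0.378 with an estimated correlation). Cyclin B1, Ccnb1, fell by 0.54 ± 0.07 (adjusted p = 0.00412), from 414.7 ± 16.4 to 285.8 ± 14.5 CPM, and Ttk fell by 0.53 ± 0.08. In the list of apoptosis and p53 targets 8 of 24 genes rose and 2, among them Bid (−0.33), fell (9 and 2 adjusted over the list alone; adjusted p = 2.27e-04, and adjusted p = 0.268 with an estimated correlation). The risen members act in opposite ways: Trp53inp1 (1.55 ± 0.15) and Phlda3 (1.40 ± 0.16) are p53 targets, Btg2 (0.78 ± 0.09) restrains proliferation, and Bcl2 (0.70 ± 0.10) protects from apoptosis.

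Stress lists were mixed. Of 23 antioxidant and NRF2 target genes 9 rose and 4 fell (9 and 7 adjusted over the list alone; adjusted p = 0.172). The metallothionein gene Mt1, counted at 80.9% of its reads, rose by 1.70 ± 0.21, the ferritin light chain gene Ftl1 by 0.68 ± 0.08 and Nqo1 by 1.63, while Pgd of the pentose phosphate pathway fell by 0.47 ± 0.07. Of 26 ATF4 target and amino acid supply genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.513, and 0.0397 without control 2), and with the block 6 rose and 5 fell. Ddit3, encoding the stress factor CHOP, rose by 1.41 ± 0.20 (adjusted p = 0.00559), and the serine synthesis gene Psat1 fell by 0.46 ± 0.13 (kept in 1 of 6 fits). Of 24 endoplasmic reticulum chaperone and unfolded protein response genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom), among them Calr by 0.29 ± 0.08 (kept in 1 of 6 fits). That list's adjusted p was 0.195, and 0.0346 without palmitate 1; with the block 8 rose and 1 fell. Of 28 type I interferon response genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; 0 falls also at an unadjusted p under 0.05, by DESeq2 and by voom). Zbp1, a sensor of viral nucleic acid, rose by 0.66 ± 0.14 (adjusted p = 0.0182, kept in 2 of 6 fits). With the block 9 rose and 4 fell. The list's adjusted p was 0.0916, but 0.0478 with no filter on low counts, 0.029 without control 3 and 5.88e-12 without palmitate 1. Of 40 cytosolic ribosomal protein genes 1, Rps9, rose by 0.28 ± 0.09 (kept in 1 of 6 fits) and 0 fell (0 and 0 adjusted over the list alone; 13 higher and 0 lower at an unadjusted p under 0.05, 6 and 0 by DESeq2, 1 and 0 by voom), with 10 rising under the block. Its adjusted p was 0.00998, but 0.689 with an estimated correlation, 0.223 in the transcript sums with offsets, 0.0889 without control 2 and 0.133 without palmitate 3.

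Among markers of other cell types, all 12 tested B cell and plasma cell genes had higher values with palmitate, at a median log2 fold change of 0.97, though most did not pass. In the other lists few or no genes passed. Of 12 B cell and plasma cell genes 2, Jchain and Cd79a, rose and 0 fell (4 and 0 adjusted over the list alone; 0 falls also at an unadjusted p under 0.05, by DESeq2 and by voom), and 6 rose with the block. The camera adjusted p was 6.19e-04, and adjusted p = 0.268 with an estimated correlation. Cd79a, part of the B cell receptor, went from 0.21 ± 0.072 to 0.835 ± 0.337 CPM (kept in 3 of 6 fits), and Igkc, the kappa light chain, from 4.90 ± 1.83 to 15.5 ± 7.39 CPM without passing (adjusted p = 0.0514; 0.000392 with the block). Of 7 CD4 and regulatory T cell genes 1, Zbtb7b, rose by 1.15 ± 0.30 (kept in 1 of 6 fits; 1 adjusted over the list alone; list adjusted p = 0.55), and with the block 2 rose and 1 fell. None of 9 monocyte, macrophage and dendritic cell genes passed edgeR's test, over all genes or adjusted over the list alone (0 and 0; 2 higher at an unadjusted p under 0.05, 2 by DESeq2, 0 by voom and 2 with the block). That list's adjusted p was 0.137, and 0.0346 without palmitate 1, with Cd74 at 20.97 ± 4.28 and 33.2 ± 7.76 CPM. None of 6 natural killer cell genes and neither of the 2 tested pancreatic genes passed in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom), and the natural killer list had an adjusted p of 0.721. Of 6 erythroid and platelet genes Hbb-bs rose by 1.92 ± 0.34, to 5.38 ± 1.09 CPM (1 adjusted over the list alone; list adjusted p = 0.51; 2 with the block). Of 2 neutrophil genes Cxcr2, whose transcript carries a sense B2 match, fell by 1.00 ± 0.14, and of the stromal and endothelial list the 1 tested gene, Pecam1, rose by 0.48 ± 0.13 (kept in 2 of 6 fits; 1 adjusted over the list alone in each).

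With the preset correlation camera placed 14 of the 32 lists it could test past the threshold, and 12 on the voom fit. With an estimated correlation it placed 0. Camera's list calls therefore rest on the assumption that genes within a list vary nearly independently. Splits of the 6 libraries into 3 and 3 other than the real one gave 3 to 12 lists with the preset correlation. Fry gave 15, but it asks whether a list's members changed at all, not whether they changed more than other genes.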

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

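The test of antisense matches and that of length offsets were chosen after the result was seen, as were the transcript sums without offsets. The per-library transcript tables held genes that the gene matrix left out or counted too low to test. Of 1077 such genes, 135 passed the same test in the transcript sums with length offsets, 68 higher and 67 lower, and 49 of them were absent from the matrix. They were singled out because the comparison of the gene matrix did not use these reads. The interferon-inducible GTPase genes Gbp6 (0.95) and Gbp5 (0.48) were higher. Of the 67 lower genes 37 carried a sense B2 match, against 1 of the 68 higher genes.

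Genes whose most-read transcript carries a sense B2 match were lower with palmitate, the more so the closer the match: medians were −0.27, −0.41, −0.49 and −0.70 from the fewest to the most shared stretches. The 91 genes with the closest matches held 0.971 ± 0.057% of the counts in control and 0.645 ± 0.053% in palmitate libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). Genomic DNA or unspliced RNA would lower antisense matches too if both orientations were caught alike, which was not tested. The median of the antisense matches was 0.13. Removing a GC trend left the sense genes at −0.27 (95% interval −0.32 to −0.21). A test within genes took transcripts with at least 50 reads. Those sharing at least 21 stretches with B2 in sense were set against those sharing none. In 418 genes with both kinds, transcripts with the repeat were lower relative to those without, by a median of −0.63 (interval −0.72 to −0.54). That held in 360 genes (exact sign test across genes, p = 2.52e-54, which counts genes as independent although they share the same libraries). Assigning reads of B2 RNA to these transcripts would give such a difference. That reading needs stranded libraries: in unstranded ones B2 RNA would have lowered the antisense matches too, and the strand setting is not given in the sources used here. If they were stranded, less B2 RNA in palmitate-treated cells, or a smaller share of it caught in those libraries, may lie behind falls such as those of Aldh1a3, Pramel4 and Ptcra, and these remain open along with a change of the host genes themselves.

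Some calls depended on which transcripts were summed. Of 376 called genes with under 90% of their transcript reads in the matrix, 154 (41%) lost the call in the transcript sums with length offsets. Of 2367 fully counted genes 545 (23%) lost it. The odds ratio was 2.3 (Fisher's exact test across genes, p = 1.34e-12). Counts of the first genes differ between the 2 sources by definition, so more lost calls among them were likely beforehand and the test decides little. The median absolute difference in log2 fold change was 0.133 in the first genes and 0.034 in the fully counted ones. The sign changed in 14 of the 376 genes and in 3 of the 2367. Among the fully counted genes the share lost with the offsets exceeded that without them (0.5%) by 22.5 percentage points, so the offsets are a source of lost calls. For Cpt1a the 2 transcripts went apart, and these data do not say whether the second one is a product of the same promoter. No biological explanation was tested for this pattern.

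B cell transcripts and naive or memory genes were both higher with palmitate. No sort is given in the sources used here that would have removed B cells. The summed gain of the B cell list was 0.274 of that of the called naive and memory genes (95% interval 0.123 to 0.557). The bound of 1 set beforehand for this ratio assumed a B cell profile that was not measured here, and 1 gene, Ighm, made up 66.2% of the B cell gain, so the ratio does not decide whether B or plasma cell RNA brought the naive and memory transcripts. In that sum the lowest palmitate library was at 1.14 times the highest control library, so the summed gain did not rest on 1 palmitate library. As Ighm made up most of the gain, this says little about the other B cell genes. A larger share of B or plasma cell RNA and a response to palmitate both stay open.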

How the results depend on the processing

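Among the alternatives, those that used transcript sums without offsets, the 90% to 110% genes, a GC trend, B2 matches, or the block with another list test were chosen after seeing the data. No gene called in edgeR with all libraries changed sign in any fit to the gene matrix; in the transcript sums 19 did with offsets and 13 without. The count of 2759 called genes lay between 2494 and 3993 in the settings written down in advance that kept all libraries (3993 with the replicate block), was 4197 with the block and the GC trend removed, and ran from 690 to 3433 with 1 library left out. The 436 genes with a 2-fold change became 192 at a minimum of 5 CPM, where fewer genes were tested (9001), 514 with the block, and 197 to 615 with 1 library left out. The 14 lists became 0 with an estimated correlation, with or without the block, and 12 to 18 with 1 library left out; the block alone gave 14. Beyond the changes given beside each result, the block changed no other list call, and of 149 named genes it added 18 calls and removed 0. Of the 149, the call was lost by 6 without control 1, 33 without control 2, 58 without control 3, 27 without palmitate 1, 33 without palmitate 2 and 35 without palmitate 3, and the cause was not tested. Values that changed sign and passed in neither fit, except Atp5g1, were these: in the transcript sums with offsets Atp5g1 (0.07), Klre1 (0.04; 53.3% of its reads in the matrix), Rpl18 (−0.07) and the complex I list (adjusted p = 0.904); without offsets Klre1 (0.03); and with upper-quartile scaling Prss2 (0.05). With 1 library left out they were Ikzf4 (−0.20 to 0.00; 79.9% of its reads in the matrix), Il4 (−0.17 to 0.84), Klrb1b (−0.11 to 0.99), Mpo (−0.42 to 0.68), Prss2 (−0.38 to 0.27) and Tnf (−0.05 to 0.19). The lists that did so, with their ranges of adjusted p, were complex I (0.494 to 0.993), ATF4 targets (0.0397 to 0.972), natural killer cells (0.258 to 0.921) and hypoxia-inducible genes (0.0136 to 0.909). Besides Atp5g1 and Mgll, the named genes that lost their call in the transcript sums with offsets included Pecam1 (adjusted p = 0.0535), Rps9 (0.104), Zbtb7b (0.134), Batf (0.0571), Etfa (0.0513) and Fabp5 (0.0578). The depth of 16724588 to 29362276 counts left genes near 1 CPM, such as Pdk4 and Cd79a, with few reads in each library.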

Other observations

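The families below, their 13 patterns of gene symbols and the splits were chosen after the result was seen, and the pattern for initiation factors was narrowed once after its first result. Interferon-inducible genes outside the lists moved in families. Of 8 guanylate-binding protein genes, which encode GTPases of the defence against intracellular microbes, 6 rose (Fisher's exact test across genes, adjusted p = 5.61e-04), and of 10 p200 genes, a family with DNA sensors, 6 rose and 1, Ifi211, fell (adjusted p = 0.00172). Gbp8 went from 13.2 ± 2.58 to 35.4 ± 3.46 CPM, Gbp9 from 67.6 ± 2.14 to 113.3 ± 12.3 CPM and Ifi213 from 20.6 ± 7.31 to 59.5 ± 4.98 CPM. Of 15 major histocompatibility genes 6 rose (exact test, adjusted p = 0.0167), among them H2-K1 by 0.44. That family did not pass with no filter on low counts (0.0844), in the transcript sums with offsets (0.108), with the GC trend removed (0.143), among genes with 90% to 110% of their reads in the matrix (0.0598) or without palmitate 3 (0.182). The matrix held 65.2% of the transcript reads of Gbp8, 63.9% of Gbp9 and 58.1% of H2-K1.

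Of 19 nucleoporin genes, which form the nuclear pore, 9 fell and 0 rose (exact test, adjusted p = 0.00109), with Nup37 going from 119.2 ± 5.49 to 76.8 ± 2.68 CPM and Nup107 falling by 0.43. The guanylate-binding, p200 and nucleoporin families passed in every alternative run. Of 46 translation initiation factor genes 14 fell and 0 rose (exact test, adjusted p = 0.00289), including Eif4e, counted at 57.8% of its reads, by 0.46 and Eif4g1 by 0.33. That family did not pass without control 2 (0.0628), control 3 (1.0), palmitate 1 (0.0943) or palmitate 3 (0.156). Genes within a family are not independent replicates.

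Results of the families that follow changed with the settings. Of 319 zinc finger Zfp genes, many of them repressors of transposons, 14 fell (4.4%, against 11.9% of other genes; exact test, adjusted p = 1.46e-04) and 47 rose (adjusted p = 0.101); with the block 24 fell and 60 rose. The shortage of falls did not pass without control 3 (0.163) or palmitate 3 (0.0663). The count of risen Zfp genes passed with no filter on low counts (0.00317), with DESeq2 (8.62e-04), in the transcript sums with offsets (0.0103) and with the block and the GC trend removed (0.0102). Of 12 lysosomal cathepsin genes 5 rose (exact test, adjusted p = 0.0223). They did not pass at a minimum of 5 CPM (0.0644), with voom (0.0734), in the transcript sums with offsets (0.497) or without them (0.106), among genes with 90% to 110% of their reads in the matrix (0.0515), with the GC trend removed (0.0798), among genes without a sense B2 match (0.21), or without control 2 (0.415), control 3 (0.858), palmitate 1 (0.502), palmitate 2 (0.121) or palmitate 3 (0.388). Of 38 proteasome genes 0 rose, fewer than among other genes (exact test, adjusted p = 0.0478), and 5 fell (adjusted p = 0.944; 0.00203 with DESeq2, 0.0468 with the block, where 12 fell and 1 rose, and 0.0436 with the block and the GC trend removed). The shortage of rises was lost in most other settings, including RLE size factors (0.0668) and the fits without control 1 (0.10), control 2 (0.666), control 3 (1.0), palmitate 1 (0.698), palmitate 2 (0.443) and palmitate 3 (0.581). Of 7 chaperonin genes 1 fell (exact test, adjusted p = 0.753), but 5 fell with the block (0.00559) and with DESeq2 (0.00124). A further member, Cct6a, was absent from the matrix and fell by 0.83 in the transcript sums with length offsets (edgeR, adjusted p = 0.00371). In those sums 2 of 8 chaperonin genes fell and 0 rose (exact test for falls, adjusted p = 0.395). Of 19 aminoacyl-tRNA synthetase genes, whose enzymes charge tRNA for translation, 5 fell (exact test, adjusted p = 0.126), but 9 with the block (0.00559). They also passed with DESeq2 (8.62e-04), with no filter on low counts (0.00631), with the GC trend removed (0.0334), with that and the block (1.75e-04) and without control 1 (0.0109). Of 67 histone genes 5 fell (exact test, adjusted p = 0.496) and 2 rose (0.0717); with the block 10 fell and 4 rose. The shortage of risen histone genes passed with the block (0.0387), upper-quartile scaling (0.0211), a minimum of 5 CPM (0.0348), transcript sums without offsets (0.029), genes with 90% to 110% of their reads in the matrix (0.0316) and without control 1 (0.0253). Of 16 autophagy genes 0 fell and 1 rose (exact test, adjusted p = 0.397 and 1.0), and 2 rose with the block.

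The 6 libraries can be split into 3 and 3 in 10 ways, too few to show a share under 0.05. The real split gave 2759 genes, 436 of them with a 2-fold change, and 14 lists; the highest other values were 2, 2 and 12. For each of the 3 results 1 split, the real one, was as large. The other splits gave 3 to 12 lists while calling 0 to 2 genes, so many lists passed camera without the real grouping. Among the 4 splits that part all 3 replicate pairs, the highest other values were 2, 2 and 10.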
